A study of Mus musculus with 4 samples.

How the data were processed

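Gene expression was measured by RNA sequencing in 4 libraries of primary mouse neural stem cells, 2 wild type and 2 Mettl4 knockout. Per the labels' protocols, cortex from embryonic day 14.5 was dissociated, grown as floating spheres, dissociated again and plated as a monolayer, and the RNA was extracted with TRIzol. Libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The labels give the libraries as replicates and do not say whether they came from separate embryos or cultures. Sex-linked RNA differed between the wild type libraries, as given below, so these were not repeats of a single RNA sample. For the knockout libraries this is not known. The p-values of single genes measure the spread between these libraries, which may be technical in part. Those of the reported gene list test compare the members of a list with the other genes. They do not directly measure the spread between cultures.

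The deposited values are whole-number read counts per gene, not normalised, in 1 file per library with Ensembl gene identifiers. Per the submitters' processing notes, STAR 2.7.10, featureCounts and the genome build GRCm39 were used. The settings for strand and for reads with several matches are not given in the sources used here. In the counts, mt-Co3 and its nuclear copy Gm28437 agreed to between 99.82% and 100.2% in each library, and 1 pair of identifiers without a symbol to between 99.95% and 99.97%, so some reads were counted for more than 1 gene. Counts of near-identical, overlapping and antisense genes are therefore uncertain. Symbols, gene types and GC content came from a GENCODE mouse annotation of an earlier build, which matched 52081 of the 55414 identifiers. It was used for names, neighbour order and GC content only, and no coordinates are given.

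Library totals ran from 12812064 to 19310668 counts. Genes were filtered with edgeR's filterByExpr defaults (a minimum count of 10), which left 19912, and CPM, counts scaled to library size, used TMM factors, except for Malat1, the sex-linked genes and the genes seen mostly in 1 library, whose CPM use the library total alone. Each gene was tested for knockout against wild type with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with robust=TRUE and the other settings of glmQLFit at the defaults of this version, which include legacy=TRUE. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called under 0.05. Fold changes are log2 values, knockout minus wild type. Standard errors are the log2 fold change over the root of F, and intervals cover 95%. Intervals and the upper limits for a count of 0 (3 counts over the library total) rest on read counts without molecular identifiers. The common dispersion was 0.0272, a biological coefficient of variation of 16.5%. The test was checked on simulated counts with the means and library sizes of these samples: over 5 runs with 200 changed genes each it made 474 calls, of which 21 were false.

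The lists of genes, the test design, the rule for named genes and the alternatives were chosen before the data were examined. There were 27 lists from textbook knowledge: stem cell, cell cycle, inhibitor, neuronal, progenitor, ventral forebrain, glial, signalling, splicing, adenosine methylation, stress, metabolic, Hox, mitochondrial and sex chromosome genes, and markers of microglia, endothelium, mesenchyme and blood. Lists with at least 5 tested members (25) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over lists. Beside each list stand the members called over all genes and those called when p-values are adjusted over the list alone. Camera with an estimated correlation works with 2 residual degrees of freedom here, so it could hardly call any list. Its smallest adjusted p over the lists was 0.79, and these values say little for or against a list. Named genes are Mettl4, then up to 10 called genes with the largest rise and 10 with the largest fall among protein-coding genes with at least 5 CPM in the higher group, both knockout libraries beyond both wild type libraries and no clone-type symbol. From each list up to 4 members with the smallest p follow. Only Mettl4 met the second part, so nearly all named genes come from the lists, and sex chromosome genes are named under their list only. A few genes that the rule takes are not reported here. With 2 libraries against 2, chance sets the groups apart for 33.3% of genes.

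The alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom, robust=FALSE, a fold change threshold, protein-coding genes only, leaving out each library in turn, the replicate number as a block, removal of each library's GC trend (a spline with 5 degrees of freedom, 98.5% of tested genes with a GC value), and for lists an estimated correlation and fry. Dispersion with legacy=FALSE, and camera with each list's own estimated correlation set as its preset, were added after the data had been seen. Exon usage and splicing were not analysed here.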

Results

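RNA sequencing counts per gene were collected from primary neural stem cells of the mouse cortex, taken at embryonic day 14.5 and grown in culture with EGF and basic FGF. Wild type and Mettl4 knockout cultures were compared, with 2 libraries in each group. Mettl4 encodes a methyltransferase that acts on adenosine. The libraries held 12812064 and 16883734 counts in the wild type, and 18150389 and 19310668 in the knockout. Of 55414 genes in the files, 19912 passed the low-count filter and were tested. A check for libraries deposited more than once found none, with a chi-square per degree of freedom of 16.6 between the wild type libraries and 26.3 between the knockout libraries against read-counting error alone. The series names proliferation, differentiation and alternative splicing as its subjects. Gene counts bear on the expression of genes of these processes, and splicing itself was not analysed here.

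Mettl4 RNA was lower in both knockout libraries. Its level, in counts scaled to library size (CPM), was 63.8 and 66.6 in wild type replicates 1 and 2, and 15.6 and 17.6 CPM in knockout replicates 1 and 2. The group means were 65.2 ± 1.98 CPM (SD, n = 2) and 16.6 ± 1.38 CPM (SD, n = 2). The log2 fold change was -1.97 with a standard error of 0.17 and a 95% confidence interval from -2.34 to -1.60 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0051). The knockout level was 25.5% of the wild type level, with an interval from 19.7% to 32.9%. The part of the gene that was removed is not given in the sources used here, so reads outside it can still be counted. The gene (ENSMUSG00000055660 in the files) lies on chromosome 17.

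**Figure D1:**
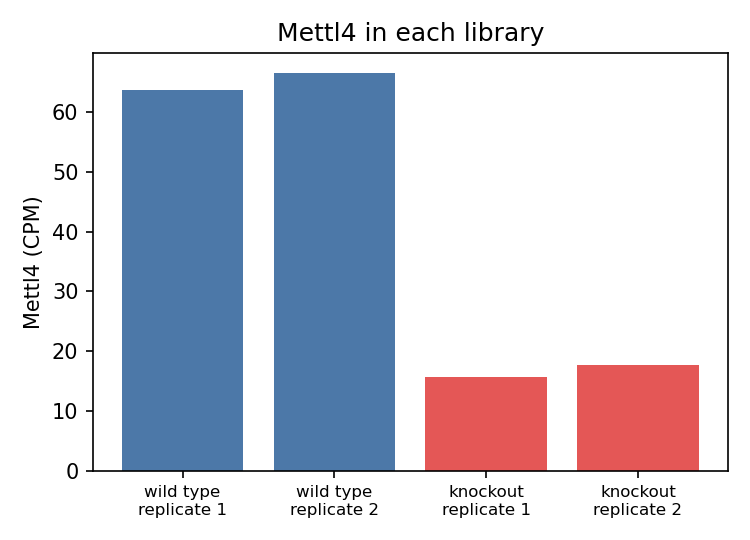
Mettl4 level in CPM for each of the 4 libraries, with wild type in blue and knockout in red. The wild type bars reach 63.8 and 66.6 CPM and the knockout bars 15.6 and 17.6 CPM.

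No gene other than Mettl4 differed between the genotypes past an adjusted p of 0.05 in the edgeR test, and the next smallest adjusted p was 0.801, for mt-Nd6. The numbers of genes higher and lower in the knockout were therefore 0 and 1. At an unadjusted p under 0.05 there were 551 genes, 228 higher and 323 lower, where chance alone gives about 996. The p-values thus ran larger than chance alone would give, and why was not tested. The lack of calls therefore does not show a lack of differences. DESeq2 called 9 genes, with 292 at an unadjusted p under 0.05, and limma-voom called 1, with 548. The DESeq2 calls included the Y-linked Ddx3y and Eif2s3y, counted in wild type replicate 1 only. The median standard error of a log2 fold change was 0.25, and it was 0.15 for genes over 64 CPM. In simulated libraries of the same size, the test recovered 6.87% of genes changed 1.5-fold, 47.5% at 2-fold and 82.1% at 4-fold. The simulation held 200 changed genes per run, each gene independent at the fitted trend of dispersion. It left out spread particular to a gene and differences that many genes share between libraries, so these shares may be too high here. Even so, smaller changes were mostly not detectable with this many libraries. The count also depended on the model. It was 9 with the replicate number as a block, though no label marks pairs, and 73 with GC correction added. Without a low count filter it was 41, and with at least 1 CPM in 2 libraries 1. The unfiltered edgeR fit moved the adjusted p of Mettl4 to 1.7e-20 at a log2 fold change of -1.96. P-values of that fit, given for some genes below, are thus not comparable with the reported ones. The count changed too with the libraries used. It was 31 without wild type replicate 1, 17 without wild type replicate 2, 47 without knockout replicate 1 and 1 without knockout replicate 2, in fits that assume the lone library of a group to vary like the others. Mettl4 was called in 4 of these 4 fits, and mt-Nd6 and Pdk1 in 3, each time except without knockout replicate 2.

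Genes of stem cell identity and of the cell cycle, the groups closest to proliferation, were not called as lists. Of 25 neural stem and radial glial genes, 16 had a positive and 9 a negative log2 fold change (camera gene set test, adjusted p = 0.26). Sox9, a transcription factor of radial glia, measured 60.3 ± 4.15 CPM in the wild type and 82.7 ± 2.04 CPM in the knockout (SD, n = 2 each; log2 fold change 0.46, SE 0.14). Gli3, a transcription factor of Hedgehog signalling, measured 21.1 CPM and 29.0 CPM. Among 25 genes of S phase and DNA replication, 22 were positive and 3 negative, with a median of 0.06 (adjusted p = 0.27). Among 25 genes of G2 and mitosis, 16 were positive and 9 negative, with a median of 0.05 (adjusted p = 0.58). The cyclin gene Ccne2 had a log2 fold change of 0.31 (SE 0.16) and the nucleotide reductase subunit Rrm2 one of -0.23 (SE 0.17). Of 20 cell cycle inhibitors and p53 targets, 7 were positive and 13 negative (adjusted p = 0.76), among them Cdkn2a at -0.40 (SE 0.21) and Cdkn1b at 0.26 (SE 0.14). In these lists 0 members were called over all genes tested and 0 adjusted over the list alone in the edgeR test, with 2 at an unadjusted p under 0.05, Sox9 and Gli3.

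Neuronal, neurogenic and ventral forebrain genes gave no call. Of 20 tested neuronal differentiation genes, 13 were negative and 7 positive, with a median log2 fold change of -0.15 (camera adjusted p = 0.26). The synaptic gene Snap25 was at 6.47 ± 0.506 CPM in the wild type and 4.31 ± 1.37 CPM in the knockout (SD, n = 2 each). Without wild type replicate 1 this list passed the threshold (adjusted p = 0.031). Of 11 neurogenic progenitor genes, 6 were positive and 5 negative (adjusted p = 0.65), with Hes6 at -0.49 (SE 0.14). Their median was 0.02 and their mean -0.04. Of 7 ventral forebrain and interneuron genes, 5 were positive and 2 negative (adjusted p = 0.15). The ventral factor Sp8 read 4.23, 14.5, 18.0 and 16.3 CPM in wild type replicates 1 and 2 and knockout replicates 1 and 2. The ventral list passed without wild type replicate 2 (adjusted p = 0.0031) and without knockout replicate 2 (adjusted p = 0.025), and Sp8 passed the edgeR threshold without wild type replicate 2 (adjusted p = 7.6e-05). In these lists 0 members were called by edgeR over all genes or adjusted over the list alone, with Nefh and Hes6 at an unadjusted p under 0.05. Without knockout replicate 1, the neuronal member Mapt, picked out after its values were seen, passed over all genes (-1.38, edgeR adjusted p = 0.004).

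The glial lists went in opposite directions. Oligodendrocyte lineage genes were higher in the knockout as a list (camera adjusted p = 0.0015, adjusted p = 0.79 with an estimated correlation), with 13 of 17 tested members positive and a median log2 fold change of 0.27. Sox10, the transcription factor that drives this lineage, measured 0.935 ± 0.575 CPM in the wild type and 2.87 ± 0.496 CPM in the knockout (SD, n = 2 each). Sox10 lay near the low end of detection, with 0.528 CPM in wild type replicate 1. Gpr17, a receptor of immature oligodendrocytes, measured 4.21 ± 2.32 and 8.80 ± 0.76 CPM, and the progenitor receptor gene Pdgfra 23.9 ± 0.412 and 31.1 ± 2.67 CPM. These members were named for their small p. Other lineage genes hardly moved, with Olig1 at 0.01 and Olig2 at 0.16. The 4 negative members were Lhfpl3 (-0.18), Myrf (-0.09), Bcas1 (-0.02) and Sox8 (-0.01). Astrocyte genes were lower as a list (adjusted p = 0.018, adjusted p = 0.79 with an estimated correlation), with 21 of 24 members negative and a median of -0.20. Sparcl1, a secreted astrocyte protein, had a log2 fold change of -0.40 (SE 0.18) and Mlc1, an astrocyte membrane protein, one of -0.34 (SE 0.16). Aldh1l1, a widely used astrocyte marker, went the other way, from 134 ± 33.6 CPM to 223 ± 34.3 CPM, and passed the edgeR threshold without a low count filter (adjusted p = 0.011). In both glial lists 0 members were called over all genes tested and 0 adjusted over the list alone by edgeR, with 3 oligodendrocyte and 2 astrocyte members at an unadjusted p under 0.05. The oligodendrocyte call held in each of the 4 fits without a library, with Gpr17 passing over all genes without wild type replicate 2 (edgeR adjusted p = 0.027), and the astrocyte call was lost without wild type replicate 2 (adjusted p = 0.56) and without knockout replicate 2 (adjusted p = 0.67). Without knockout replicate 1, the astrocyte members Apoe (-1.83, adjusted p = 0.0037) and Atp1b2 (-1.19, 0.0067) passed the edgeR threshold over all genes; they were picked out after their values were seen.

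**Figure D2:**
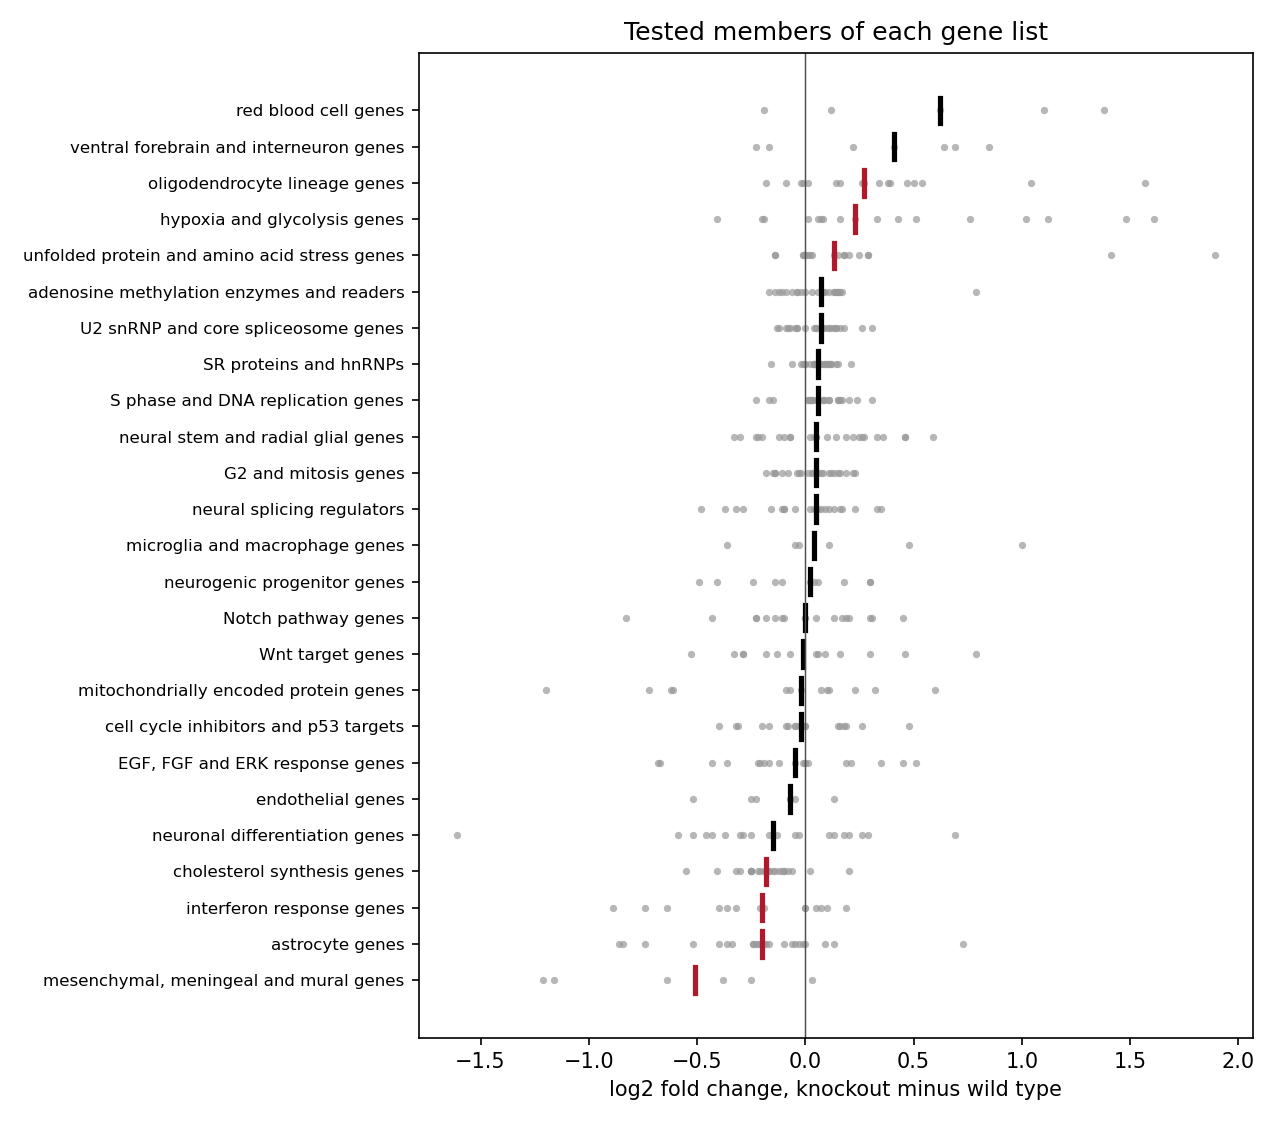
Log2 fold change, knockout minus wild type, of each tested member (grey points) of the 25 tested gene lists, with the list median as a bar that is red where the camera adjusted p was under 0.05. Of the 7 lists with red bars, 3 lie above 0 and 4 below.

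Genes of the splicing machinery, which bear on the series' question about splicing, gave no call. Among 25 genes of the U2 snRNP and core spliceosome, 16 were positive and 9 negative, with a median log2 fold change of 0.07 (camera adjusted p = 0.43). Snrpd1, a core protein of spliceosomal particles, was at 0.31 (SE 0.21) and the spliceosome scaffold Prpf8 at 0.18 (SE 0.18). Among 25 SR proteins and hnRNPs, 20 were positive and 5 negative, with a median of 0.06 (adjusted p = 0.26), and Hnrnph1 was at 0.21 (SE 0.16). Among 22 neural splicing regulators, 13 were positive and 9 negative, with a median of 0.05, a mean of -0.01 and an adjusted p of 0.67 (camera). Ptbp2, a splicing repressor of developing neurons, was at 0.23 (SE 0.17), and the neuronal regulator Rbfox3 at -0.37 (SE 0.30). Among 24 adenosine methylation enzymes and readers, 15 were positive and 9 negative (adjusted p = 0.36). Igf2bp2, which binds methylated RNA, was at 17.7 ± 3.18 CPM in the wild type and 30.6 ± 3.68 CPM in the knockout (SD, n = 2 each; edgeR p adjusted over the list alone 0.069). In these lists 0 members were called by edgeR over all genes or adjusted over the list alone, and Igf2bp2 had an unadjusted p of 0.0029.

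The signalling lists for the pathways that maintain these cultures gave no call. Notch pathway genes split into 9 positive and 9 negative (camera adjusted p = 0.91), with the feedback inhibitor Nrarp at 0.45 (SE 0.16) and the ligand gene Jag1 at -0.43 (SE 0.20). Wnt target genes split into 7 positive and 7 negative (adjusted p = 0.89), with a median of -0.01 and a mean of 0.01. Axin2, a common readout of this pathway, was at -0.29 (SE 0.19). Of 19 genes that respond to EGF, FGF and ERK, 6 were positive and 13 negative (adjusted p = 0.58). Dusp6, a phosphatase that dampens ERK signalling, was at 177 ± 35.4 CPM in the wild type and 111 ± 25.3 CPM in the knockout (SD, n = 2 each), and passed the edgeR threshold only without knockout replicate 1 among the fits that left out a library (adjusted p = 0.037). In these lists 0 members were called by edgeR over all genes or adjusted over the list alone, with Nrarp, Sox9, Dusp6 and Il17rd at an unadjusted p under 0.05.

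Metabolic and stress lists held 4 of the 7 list calls. Hypoxia and glycolysis genes were higher in the knockout (camera adjusted p = 0.0035, adjusted p = 0.79 with an estimated correlation), with 14 of 17 members positive and a median log2 fold change of 0.23. Adjusted over the list alone, 2 members were higher by edgeR: Egln3, an oxygen sensor enzyme (15.1 ± 0.357 against 25.5 ± 4.76 CPM, SD, n = 2 each, list-adjusted p = 0.042), and Pfkl, a phosphofructokinase subunit (19.5 ± 4.50 against 39.5 ± 16.2 CPM, list-adjusted p = 0.042). Over all genes tested 0 members were called. Much of the difference lay in knockout replicate 2. Pdk1, which restrains pyruvate oxidation, read 11.9 CPM in knockout replicate 1 and 39.6 CPM in knockout replicate 2, against 10.5 and 7.99 CPM in the wild type. Bnip3, a mitophagy receptor, read 16.9 and 40.6 CPM against 13 and 13.4 CPM. The list call was lost without knockout replicate 2 (adjusted p = 0.62) and without wild type replicate 2 (adjusted p = 0.15). Over all genes, Pdk1, Pfkl and Bnip3 passed the threshold without knockout replicate 1, at edgeR adjusted p = 1.4e-05, 0.0023 and 0.00037. Pdk1 and Pfkl also passed without wild type replicate 1 (0.00017 and 0.0076), and Pdk1 without wild type replicate 2 (0.031). Without a low count filter Pfkl (0.00053) and Bnip3 (0.00072) passed by edgeR, in the fit whose p-values are not comparable with the reported ones.

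**Figure D3:**
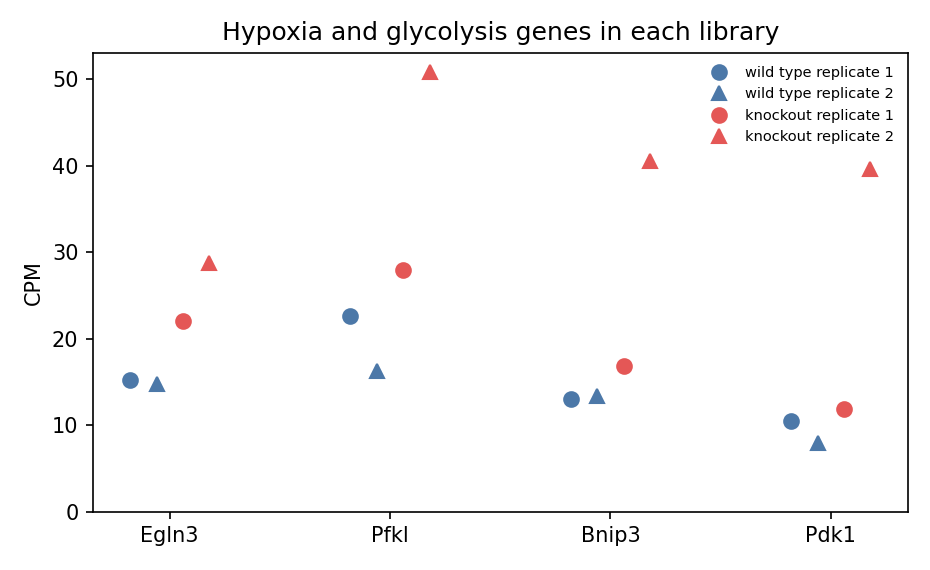
Level in CPM of Egln3, Pfkl, Bnip3 and Pdk1 in each of the 4 libraries, wild type in blue and knockout in red, circles for replicate 1 and triangles for replicate 2. Knockout replicate 2 is highest for each of the 4 genes, with Pdk1 at 39.6 CPM against 11.9 CPM in knockout replicate 1.

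Cholesterol synthesis genes were lower as a list (camera adjusted p = 0.0035, adjusted p = 0.79 with an estimated correlation), with 22 of 24 members negative and a median log2 fold change of -0.18. Insig1, a sterol-responsive regulator, was at -0.32 (SE 0.17), and Hsd17b7 at -0.41 (SE 0.16). Interferon response genes were lower as a list (adjusted p = 0.018, adjusted p = 0.79 with an estimated correlation), with 10 of 14 negative, among them Rtp4 at -0.89 (SE 0.40). Genes of the unfolded protein and amino acid stress response were higher as a list (adjusted p = 0.046, adjusted p = 0.79 with an estimated correlation), with 14 of 19 positive and a median of 0.13. Their larger values came from genes near the low end of detection: Chac1, which degrades glutathione, read 0.962 ± 0.24 CPM in the wild type with a log2 fold change of 1.41 (SE 0.46), and Trib3, a stress-induced pseudokinase, read 0.273 ± 0.041 CPM with one of 1.89 (SE 0.69). In these 3 lists 0 members were called by edgeR over all genes or adjusted over the list alone, with 1 cholesterol, 0 interferon and 2 stress members at an unadjusted p under 0.05. Without knockout replicate 2 the calls were lost (adjusted p = 0.075 for cholesterol, 0.41 for interferon and 0.94 for stress), as they were without wild type replicate 2 (0.097, 0.56 and 0.19). The median shift of the cholesterol list against the wild type mean was nevertheless alike in knockout replicates 1 and 2 (-0.17 and -0.19), while that of the stress list was 0.02 and 0.24. Without wild type replicate 1 the cholesterol (0.087) and stress (0.097) calls were lost too. The stress call was also lost when at least 1 CPM in 2 libraries was required (0.099).

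Many markers of other cell types lay under the low-count filter. Mesenchymal, meningeal and mural genes were lower in the knockout as a list (camera adjusted p = 0.0017, adjusted p = 0.79 with an estimated correlation), with 5 of 6 tested members negative and a median log2 fold change of -0.51. Acta2, smooth muscle actin, fell adjusted over the list alone (5.15 ± 2.11 CPM to 2.20 ± 0.551 CPM, SD, n = 2 each, edgeR list-adjusted p = 0.047), and 0 members were called over all genes tested. Tagln, another contractile gene, read 1.82 ± 0.416 and 0.808 ± 0.173 CPM, and the transcription factor gene Foxc1 21.8 ± 1.28 and 16.7 ± 1.05 CPM. This list call held in each of the 4 fits without a library. Of the 20 listed genes, 14 were under the low-count filter, among them the collagen gene Col1a1 with 2, 9, 4 and 0 counts. Microglia and macrophage genes (6 tested, adjusted p = 0.44) and endothelial genes (7 tested, adjusted p = 0.43) gave no call. Red blood cell genes (5 tested, adjusted p = 0.14) included the globin gene Hba-a2 at 0.499 ± 0.361 CPM in the wild type and 1.26 ± 0.0707 CPM in the knockout. They passed without wild type replicate 1 (adjusted p = 9.2e-09), where the lone wild type library had 0.244 CPM of Hba-a2. The microglial, endothelial and red blood cell lists had 0 members called by edgeR over all genes or adjusted over the list alone, with 0, 0 and 1 at an unadjusted p under 0.05. Of 20 Hox genes, which mark more posterior neural tissue, 0 passed the low-count filter, and the highest count in a library was 7.

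The libraries differed in sex-linked RNA within the wild type group. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together read 210 CPM in wild type replicate 1. They had 0 counts in wild type replicate 2, 2 counts in knockout replicate 1 and 0 in knockout replicate 2. A count of 0 allows up to 0.18 CPM in wild type replicate 2 and 0.16 CPM in knockout replicate 2. Xist, the RNA that coats the inactive X chromosome, read 295 CPM in wild type replicate 1 and 3240, 3630 and 3300 CPM in the other libraries, in the same order. Wild type replicate 1 thus differed in sex-linked RNA from wild type replicate 2 and from both knockout libraries. Sex was therefore partly confounded with genotype, and it adds to the spread within the wild type. Wild type replicate 1 held Y-linked RNA together with Xist at 8.7% of the mean of the other libraries. These values do not settle whether that library came from a mix of sexes. Xist was the 1 member of the sex chromosome list that passed the low-count filter (edgeR log2 fold change 0.94, SE 1.07). Without wild type replicate 2 its log2 fold change was 3.62 (adjusted p = 6.9e-08).

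Mitochondrially encoded protein genes moved in different directions. The list of 13 was not called (camera adjusted p = 0.26), with 6 members positive, 7 negative and a median log2 fold change of -0.02. Adjusted over the list alone, 4 members were lower and 1 was higher by edgeR, while over all genes tested 0 were called. The lower members were the complex I subunit genes mt-Nd6, mt-Nd2 and mt-Nd5 and the ATP synthase subunit gene mt-Atp8, and the higher member was mt-Nd3, also of complex I. Expression of mt-Nd6 was 259 ± 13.4 CPM in the wild type and 113 ± 30.1 CPM in the knockout (SD, n = 2 each; log2 fold change -1.20, SE 0.19, edgeR list-adjusted p = 0.001). The other values were -0.62 (SE 0.16) for mt-Nd2, -0.72 (SE 0.19) for mt-Atp8, -0.61 (SE 0.18) for mt-Nd5 and 0.60 (SE 0.16) for mt-Nd3. Naming mt-Nd5 was decided after its values were seen. The cytochrome oxidase genes mt-Co1 and mt-Co2 were at 0.23 (SE 0.36) and 0.11 (SE 0.27). Mitochondrial genes took 1.26% and 1.91% of the counts in the wild type and 1.46% and 2.12% in the knockout. The list passed without wild type replicate 1 (adjusted p = 0.0078) and without knockout replicate 2 (adjusted p = 0.012). Reads from these genes can be shared with nuclear copies, and reads of neighbouring genes on opposite strands cannot be told apart unless counting used strand, so the values per gene are uncertain. Tsix, antisense to Xist, read 39.7 and 442 CPM in the wild type and 470 and 420 CPM in the knockout. It was thus low in the library where Xist was low, as counting without strand could give. Whether counting used strand was not tested. Over all genes, DESeq2 called mt-Nd6 (adjusted p = 0.00033), and edgeR called it without a low count filter (2.1e-08), without wild type replicate 1 (0.0071), without wild type replicate 2 (0.006) and without knockout replicate 1 (6.9e-05).

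**Figure D4:**
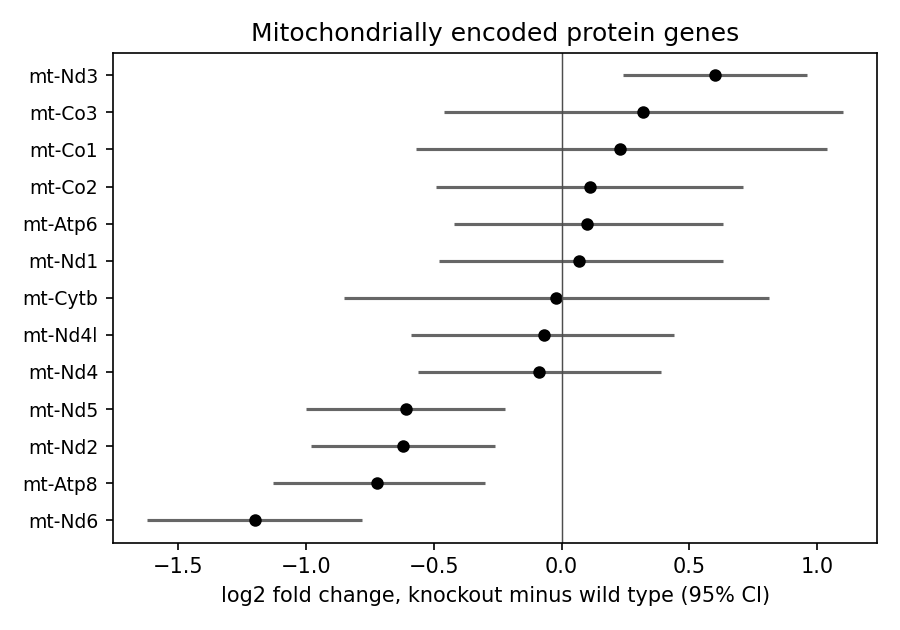
Log2 fold change, knockout minus wild type, of the 13 mitochondrially encoded protein genes, with the 95% confidence interval from the edgeR fit as a line. The interval lies below 0 for mt-Nd6, mt-Atp8, mt-Nd2 and mt-Nd5 and above 0 for mt-Nd3.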

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

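The replicate number is shared by the labels of both groups, but they do not say that it marks a pair, and the 2 pairs are too few to show one. Deviations of same-numbered libraries from their group means had a correlation of 0.31 across 17712 genes. The replicate block moved the count of changed genes from 1 to 9 (2 higher, 7 lower), and the replicate block with GC correction to 73 (30 higher, 43 lower). Both call mt-Nd6 (adjusted p = 0.0014 and 4.8e-08) and Dusp6 (0.024 and 0.0024), and the fit with GC correction also mt-Atp8 (0.0022), mt-Nd2 (0.0057), mt-Nd5 (0.013), Igf2bp2 (0.015), Egln3 (0.017), Sox9 (0.048), Zdbf2 (0.011) and Grb10 (0.046). The block left 6 of the 7 list calls, and the stress list was lost (adjusted p = 0.095). The Notch list turned direction under the replicate block with an adjusted p of 0.96.

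Mettl4 kept its direction and its call in all 16 alternatives run for it, with log2 fold changes from -2.06 to -1.89 and adjusted p from 1.7e-20 (no low count filter) to 0.021 (library size alone). With legacy=FALSE, chosen after seeing the data, its adjusted p was 0.0064 and the count stayed at 1; the planned legacy=TRUE is the default already used, so it changes nothing. The count of changed genes was 41 without a low count filter (18 higher, 23 lower) and 9 with DESeq2 (1 higher, 8 lower). The DESeq2 calls included the Y-linked Ddx3y and Eif2s3y, with 626 and 506 counts in wild type replicate 1 and 0 in the other libraries. G530011O06Rik, Gm15726 and Gm21748 were called too. They read 29, 16 and 15.7 CPM in wild type replicate 2, 10.5, 5.23 and 4.37 CPM in wild type replicate 1, and less in the knockout. Why the other genes were called was not tested. Leaving out 1 library gave from 1 to 47 changed genes, 0 to 15 higher and 1 to 32 lower, with the lone library assumed to vary like the others. The other alternatives left the count at 1.

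The number of lists called was 7, and 0 with an estimated correlation, 0 with fry, 3 with each estimated correlation set as preset (chosen after seeing the data), and from 3 to 8 when 1 library was left out. With at least 1 CPM in 2 libraries it was 5 of 21, and the mesenchymal list then had too few members to be tested. The smallest adjusted p over all lists with fry was 0.41, a value that the oligodendrocyte, cholesterol and mesenchymal lists had. The astrocyte, interferon, stress and hypoxia lists had 0.82 with fry. For the estimated correlation, the 2 residual degrees of freedom account for part of the loss, since 3 calls returned when the correlation was kept and the degrees of freedom were not (for the mesenchymal list the estimate of -0.12 lies below the preset, which loosens the test).

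When 1 library was left out, some lists and genes not called turned direction. The adjusted p of these lists ran from 0.60 to 0.98 for cell cycle inhibitors, 0.08 to 0.71 for ERK response, 0.18 to 0.81 for G2 and mitosis, 0.077 to 0.93 for S phase, 0.59 to 0.87 for neural splicing regulators and 0.14 to 0.85 for the spliceosome. It ran from 0.56 to 0.94 for neurogenic progenitors, 0.19 to 0.67 for Notch, 0.53 to 0.85 for Wnt, 0.0078 to 0.78 for mitochondrial genes and 9.2e-09 to 0.90 for red blood cell genes. Log2 fold changes ran from -0.33 to 0.01 for Ccnb2, -0.04 to 0.87 for Cdkn1c, -0.27 to 0.20 for Csf1r, -0.01 to 2.10 for Gsx2 and -0.34 to 3.27 for Hbb-bt. They ran from -0.01 to 0.29 for Hnrnpa2b1, -0.16 to 1.85 for P2ry12, -0.02 to 0.37 for Prpf8, -0.01 to 0.58 for Snrpd1 and -0.08 to 0.53 for Snrpd3. Outside the fits without a library, 0 named genes turned direction, and 14 values of single genes passed the threshold where the reported one did not.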

Other observations

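The tests in this part on mitochondrial genes, the list calls, remaining Mettl4 reads and neighbouring genes were chosen only after the results were seen. Apart from sex-linked RNA, wild type replicate 2 stood apart from the other libraries. Mid1, an X-linked ubiquitin ligase gene, read 131 CPM there and 43.5, 27.1 and 20.3 CPM in wild type replicate 1 and knockout replicates 1 and 2. Mir6236 read 32.5 CPM there against 1.80, 2.04 and 0.777 CPM. Malat1, a nuclear RNA, read 4597 CPM in knockout replicate 2 and from 7018 to 8082 CPM in the other libraries. The first principal component (50.4% of the variance) placed knockout replicate 2 at 34.3 and wild type replicate 2 at 9.2. Knockout replicate 1 lay at -14.1 and wild type replicate 1 at -29.3, so the component did not part the genotypes. It parted the replicate 1 libraries of both groups from the replicate 2 libraries. The mitochondrial share of the counts split likewise, at 1.26% and 1.46% against 1.91% and 2.12%. With 4 libraries such a split can arise by chance. The second component (28.6%) placed wild type replicate 2 at 30.6 and the others at -5.4, -8.8 and -16.4.

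Mitochondrially encoded protein genes moved apart in the knockout, and a different mitochondrial share of the reads would move them alike. Cochran's Q per degree of freedom over their log2 fold changes was 6.63. This value restates that they moved apart and is no separate test of the share, though a common shift alone would not part them. After each library's GC trend was removed, Q per degree of freedom was 7.42, which argues against that trend as the whole cause. Reads shared with nuclear copies of mitochondrial sequence stay open: 6 such nuclear features were tested, but counts of uniquely placed reads are needed. Whether genotype plays a part cannot be told from these libraries. Both knockout libraries lay beyond both wild type libraries for 5 of the 13 genes, the 5 that passed over the list alone. These were picked for their difference, and chance alone sets the groups apart for 33.3% of genes. A second maternal line of each genotype is needed to separate genotype from inherited mitochondrial differences.

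The 7 list calls came with no called member, so co-variation within lists and a single library were tested as explanations. If members of a list vary together between cultures, the preset correlation of 0.01 is too low: with each list's estimated correlation set as its preset, 2 of the 6 calls with a higher estimate held, at 0.086 (oligodendrocyte) and 0.013 (cholesterol, so hardly tightened), and the mesenchymal list, at -0.12, was not tested by this. The others had estimates of 0.43 (astrocyte), 0.22 (interferon), 0.23 (stress) and 0.45 (hypoxia), so their calls may come from co-variation. The oligodendrocyte and mesenchymal calls held without knockout replicate 2 (larger adjusted p = 0.025) and without each other library. These 2 lists were set apart after the results were seen, as the ones whose calls held. Their holding is therefore no separate test of a single library as the source. Medians against the wild type mean in knockout replicates 1 and 2 were 0.29 and 0.38 for oligodendrocyte and -0.39 and -0.81 for mesenchymal. Both knockout libraries thus lay beyond both wild type libraries, and the shifts were not in knockout replicate 2 alone. Groups also lie apart by chance (33.3% for a single gene), so chance, genotype and other differences between the cultures stay open. Of the other 5 lists, 4 had a median shift in knockout replicate 1 under 0.5 times that in replicate 2 (-0.03 and -0.36 for astrocyte, -0.13 and -0.40 for interferon, 0.02 and 0.24 for stress, 0.09 and 0.39 for hypoxia), while the cholesterol list had -0.17 and -0.19; these 5 calls were also lost without wild type replicate 2.

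Mettl4 reads remained at 25.5% of the wild type level in the knockout. Reads from wild type replicate 1 would bring Y-linked counts, and these stood at 0.026% of that library's level in the knockout, which argues against that library as the source. Wild type replicate 2 lacks Y-linked counts, so it was not tested this way. Transcripts of the knocked-out allele outside its deleted part may account for the reads, which counts per exon would show.

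A further hypothesis came from Zdbf2 and Grb10, both imprinted genes, which were higher in the knockout at an unadjusted p of 0.000995 and 0.00141 and were not called after adjustment in the reported edgeR fit. Both were called without a low count filter (adjusted p = 0.013 and 0.0024), and Grb10 without knockout replicate 1 (0.0062). The 27 other imprinted genes tested gave an unadjusted camera p of 0.19, with 16 positive, a median log2 fold change of 0.03 and 0 at an unadjusted p under 0.05. By the criterion set before the result was seen, a p of 0.05 or more, this counts against a shift of imprinted genes in a common direction. A small shift is not excluded, and shifts of members in opposite directions were not tested by it. Among the 31 tested genes nearest to Mettl4, 2 had an unadjusted p under 0.05, which is 2.33 times the share of all tested genes (Fisher's exact test, two-sided p = 0.21), so a differing chromosome segment could neither be shown nor excluded.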
